A study of Mus musculus with 3 samples.

How the data were processed

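Total RNA of day 10 embryoid bodies was extracted with TRIzol and RNeasy columns, 1 ug was amplified, and 300 ng of Cy3-labelled and 300 ng of Cy5-labelled cRNA were hybridised together on Agilent mouse 4x44K v2 arrays, per the labels' protocols. The labels give 3 biological replicates per genotype, cultured in parallel, and 3 arrays, each with 1 mutant and 1 wild-type RNA. The labels also give the dyes, from which each ratio was turned as mutant over wild type. The mutant was in Cy3 on arrays 1 and 3 and in Cy5 on array 2, so a dye effect does not cancel. The 3 arrays were on 1 slide, so slide is no batch here.

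The deposited scanner files hold spot and local background brightness as intensity, made with Agilent Feature Extraction 10.7.3.1, per the file headers. They also hold a log10 ratio of red over green, which Feature Extraction had background-corrected and dye-normalized, per the file headers. The authors' deposited value table holds log2 ratios, and the submitters' processing notes name limma without a version; other steps are not given in the sources used here. Set against the scanner log ratios of 4814 bright spots, its columns had slopes of 0.91, 0.97 and 0.998, which fits log2 of mutant over wild type, and medians of -0.01, 0.02 and -0.01. Its centring and background steps stay unknown. All of its columns belong to the 3 samples.

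In R 4.3.3 with limma 3.58.1, mean spot intensities and median background intensities of all spots were corrected with normexp (offset 50) and normalized by loess within each array, with control spots at weight 0. Control and outlier spots were then left out and spots of a probe averaged. A probe was kept when it was well above background in at least 1 genotype on all 3 arrays (25494 of 39429 probes), and the brightest probe stood for each gene, 19665 in all. Symbols came from the file's accession through a RefSeq table of GRCm38.p6 for 27234 probes, from the symbol for 3576 and from a synonym for 565; 8054 kept the name in the file. Coordinates are those of the files (mm9), and 90 of 15994 genes with a chromosome in both sources had different ones. Median spot intensity was 190, 200 and 285 in green and 148, 203 and 208 in red for arrays 1, 2 and 3, over a local background of 36 to 40 units. Of the spots, 66.5%, 72.1% and 74.8% were well above background in the mutant channel and 73.6%, 64.8% and 76.0% in the wild-type channel. No spot was saturated.

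Ratios were tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment at 0.05. Gene lists with at least 4 measured members and chromosomes with at least 50 were tested with camera at a preset correlation of 0.01, with the correlation estimated, and for lists with fry. A gene-level test with 3 arrays leaves few degrees of freedom, 4.66 with the prior. The list test with an estimated correlation has fewer, as it takes them from the arrays alone. Lower bounds used channel intensities after loess and Aquantile scaling, per array the higher of the dim probe's signal and the lowest signal among probes well above background. These were averaged over the 3 arrays, so a bound holds for the mean and not for each array.

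These choices, the gene lists and the rule for named genes were fixed before the data were examined. The rule takes Dido1, the 10 higher and 10 lower called genes of largest size with an official symbol and one sign on all arrays (or, with none called, the 5 per direction with the smallest p), up to 3 members of each list with the smallest p in the planned fit, and Pou5f1, Nanog, Gata6, Afp, T, Tubb3 and Tnnt2. After the values were seen, the local background was limited to 100 units before normexp as a further setting, and the rule of size was applied to it as well. A limit of 150 had been tried before 100, and limits of 150, 200 and 1000 were run for comparison. The normexp estimate of the background spread was 916 in green and 795 in red on array 2 and at most 1.54 on the other arrays, and 6.12 and 6.29 on array 2 once limited. The settings tried beside these were no background correction, an offset of 16, the scanner's log ratio, median centring without loess, scaling between arrays, no filter, a filter on both genotypes, the mean of a gene's probes, a dye term, a separate-channel fit, an intensity trend, leaving out each replicate, the authors' values, probes tested singly, a 2-fold minimum and a threshold of 0.1.

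The tests were tested on simulated data with the spread of each fit and 19665 genes. Of 100 genes changed by a log2 of 1 and 100 by a log2 of 2, 0 and 0 passed the adjusted threshold in either fit, while 83% and 99% in the planned fit had an unadjusted p under 0.05, and the mean estimates were 0.99 and 2.01. In the limited fit these were 81% and 96%, with estimates of 1.01 and 1.97 and 1 false call. No other simulated genes were changed, and genes varied independently. In the real data 2971 genes of the planned fit and 3898 of the limited fit had an unadjusted p under 0.05 in limma. How many genes pass Benjamini-Hochberg adjustment depends on how many change, so the recovery of 0 does not carry over to the real fits.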

Results

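Gene expression was compared between wild-type mouse embryoid bodies and embryoid bodies of a Dido mutant after 10 days of culture in suspension without LIF, the cytokine that holds mouse embryonic stem cells in self-renewal. Embryoid bodies are free-floating aggregates of differentiating embryonic stem cells. The mutant makes a Dido3 protein with a truncated C-terminal end and also overexpresses an HA-tagged N-terminal part of the Dido protein, the region shared by its isoforms that holds the PHD finger. The series title places the comparison in the question of how Dido balances self-renewal and differentiation. There were 3 biological replicates per genotype. Each of 3 arrays compared 1 mutant with 1 wild-type RNA in 2 colours, with the mutant in Cy3 for replicates 1 and 3 and in Cy5 for replicate 2. All values below are log2 ratios of mutant over wild type, positive when higher in the mutant, with SD over n = 3 arrays.

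The mutant embryoid bodies differed from wild type by several-fold in single genes, but in the fit fixed before the data were examined, called the planned fit below, no gene passed the adjusted threshold. The 5 higher genes with the smallest p were Airn, an imprinted antisense RNA, at 3.42 ± 0.29, Tnnt2, cardiac troponin T, at 2.74 ± 0.03, the imprinted RNA H19 at 3.23 ± 0.34, the stem-cell ubiquitin ligase gene Trim71 at 2.75 ± 0.24 and the ghrelin gene Ghrl at 2.33 ± 0.03. The 5 lower ones were the methyltransferase gene Eef1akmt2 at -3.19 ± 0.55, the thrombomodulin gene Thbd at -2.68 ± 0.45, the imprinted cell cycle inhibitor Cdkn1c at -3.39 ± 0.69, the lipase gene Mgll at -2.21 ± 0.31 and the imprinted receptor gene Igf2r at -2.10 ± 0.36. All 10 had the smallest adjusted p of the fit, 0.179, and none passed. Of 19665 genes tested with limma, 0 passed after Benjamini-Hochberg adjustment, while 2971 had an unadjusted p under 0.05, of which 1845 were higher and 1126 lower. A count that does not use the spread found 302 genes at least 2-fold changed in one direction on every array, 233 of them higher and 69 lower. With the sign of array 1, 2 or 3 turned, the same count was 1, 83 and 15. The turn of array 2, which has the dyes exchanged, counts genes that follow the dye.

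The count of 0 depended on the background step for 1 array. On array 2, 25 spots had a local background over 100 units, up to 75739, against at most 60 on the other arrays, and the normexp background model fitted to these values compressed that array's log2 ratios to an SD of 0.47, against 0.91 and 0.88 for arrays 1 and 3. With the local background limited to 100 units on all arrays, a setting chosen after the data were seen and called the limited fit below, the SD of array 2 was 0.79 and 357 genes passed in limma, 271 higher and 86 lower in the mutant. The count of the limited fit also depended on the limit, with 323 genes at a limit of 150, the value tried first, 271 at 200 and 30 at 1000. Without background correction 304 genes passed, 303 of them among the 357, and with the scanner software's own log ratio 768, 337 of them among the 357. The authors' deposited log ratios gave 0 genes in limma, with a smallest adjusted p of 0.0599 and 3841 genes at an unadjusted p under 0.05. In the limited fit 797 genes were at least 2-fold changed in one direction on every array, 593 higher and 204 lower. With the sign of array 1, 2 or 3 turned, that count was 4, 175 and 43. All 10 genes named above passed in the limited fit, among them Airn at 3.60 ± 0.33 (12.1-fold, adjusted p = 0.0345), Tnnt2 at 3.14 ± 0.67 (8.82-fold, adjusted p = 0.0370), Cdkn1c at -3.55 ± 0.44 (11.7-fold lower, adjusted p = 0.0345) and Eef1akmt2 at -3.54 ± 0.06 (11.6-fold lower, adjusted p = 0.0335). Ghrl was at 2.68 ± 0.60. The SD of 0.03 that Tnnt2 and Ghrl had in the planned fit did not hold, as array 2 of the limited fit read 3.92 and 3.38. Without replicate 1 the limited fit gave 0 genes in limma (1658 at an unadjusted p under 0.05), without replicate 3 also 0 (2441 unadjusted), and without replicate 2 either fit gave 4977. With a dye effect as a term 2452 genes passed in the limited fit and 665 in the planned fit. With that term array 2, alone in its dye orientation, is fitted exactly, so the spread is only that between arrays 1 and 3. Without replicate 2 both arrays carry the mutant in Cy3, so dye and genotype are not separated. The number of arrays, 3, limits the precision of every value.

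Dido1, the gene altered in the mutant, was read by 4 probes on chromosome 2 (mm9 coordinates, minus strand), and these went in both directions. The probe at 180419747 to 180419806 and the probe at 180405604 to 180405663 were higher in the mutant in the limited fit, at 2.30 ± 0.36 (4.92-fold, adjusted p = 0.0306) and 2.98 ± 0.29 (adjusted p = 0.0294). The second of these was not well above background in wild type on array 2, so its ratio there is imprecise; on arrays 1 and 3 it read 2.92 and 3.29. The probe at 180415861 to 180415920 was lower, at -3.55 ± 0.15 (11.7-fold lower, adjusted p = 0.0293). The probe nearest the 3' end of the gene, at 180393086 to 180393145, did not pass, at -0.54 ± 0.94 (adjusted p = 0.498). In the planned fit the same probes had 1.78 ± 1.22, 2.20 ± 1.58, -2.77 ± 1.41 and -0.54 ± 0.94 and none passed (adjusted p of 0.304, 0.306, 0.238 and 0.487). The file assigns the probes starting at 180419747 and 180415861 to one transcript, and the probes starting at 180405604 and 180393086 each to another. Transcripts of the added construct and of the endogenous gene share the common region, so a probe ratio does not separate them, and the exon under each probe was not assigned because no annotation of this build was used.

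**Figure D1:**
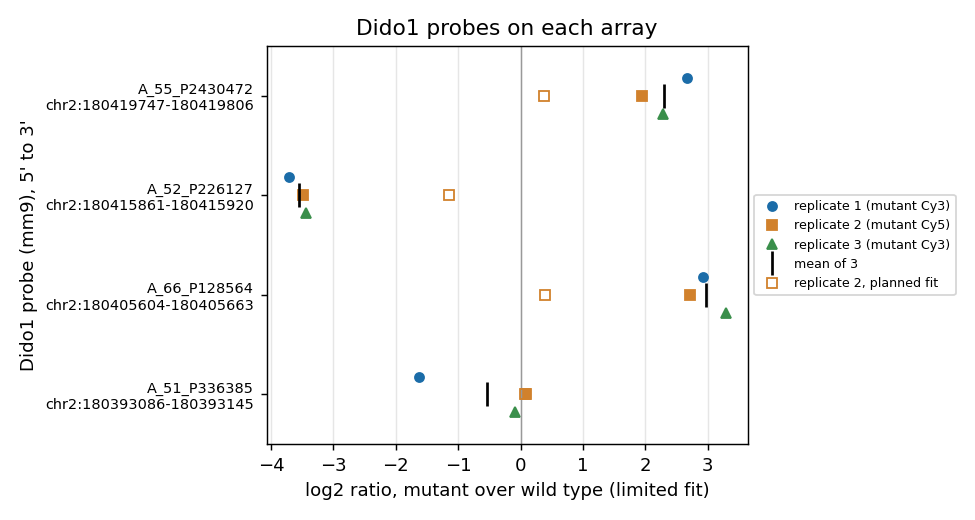
Log2 ratios of mutant over wild type (x axis) of the 4 Dido1 probes, listed from the 5' to the 3' end of the gene on the y axis with mm9 positions; filled symbols are the 3 arrays in the limited fit, black bars their mean, and open squares replicate 2 in the planned fit. The probe at 180415861 lies between -3.72 and -3.44 on the 3 arrays of the limited fit, and at -1.15 for replicate 2 in the planned fit.

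The largest call of the limited fit in each direction was sex-linked. Among the 10 higher genes, Xlr5b at 4.79 ± 0.61 (27.7-fold, adjusted p = 0.0345), Xlr5c at 4.67 ± 0.33, Xlr4a at 3.84 ± 0.81, Xlr3b at 3.69 ± 1.15 and Xlr5a at 3.68 ± 0.19 belong to one X-linked family of near-identical copies, whose probes can read one another's transcripts, so the member is uncertain. The others were the mucosal peptide gene Tff3 at 3.98 ± 1.10, the copper transporter gene Atp7a at 3.71 ± 0.52, Airn, Thoc2l at 3.60 ± 0.61 and a probe named Gcm1 at 3.73 ± 1.24. The Gcm1 probe is a GAA repeat that the file places on chromosome 7, while the reference places the gene on 9, so it does not stand for that gene. A second kept Thoc2l probe read 0.37 ± 0.25. Of the 10 lower genes, Eif2s3y and Ddx3y are on chromosome Y and were not well above background in the mutant on any array. On the mean of the 3 arrays they were at least 89.6-fold and at least 23.2-fold lower (adjusted p of 0.0335 and 0.0345), bounds open to dye bias. These are not bounds for each array: on array 1 Eif2s3y read -6.128 and Ddx3y -3.485. For Eif2s3y the bound is close to the measured 89.8-fold. The rest were 5830417I10Rik at -5.03 ± 0.61, Gm5067 at -4.72 ± 0.44, 2310039H08Rik at -4.69 ± 0.40, Paip1 at -3.63 ± 0.44, Cdkn1c, Eef1akmt2, the synaptotagmin gene Syt11 at -3.10 ± 1.01 and Thbd at -3.06 ± 0.41. A second Paip1 probe read -0.13 ± 0.13. For 5 of the 357 called genes, kept probes with an unadjusted p under 0.05 went in opposite directions.

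**Figure D2:**
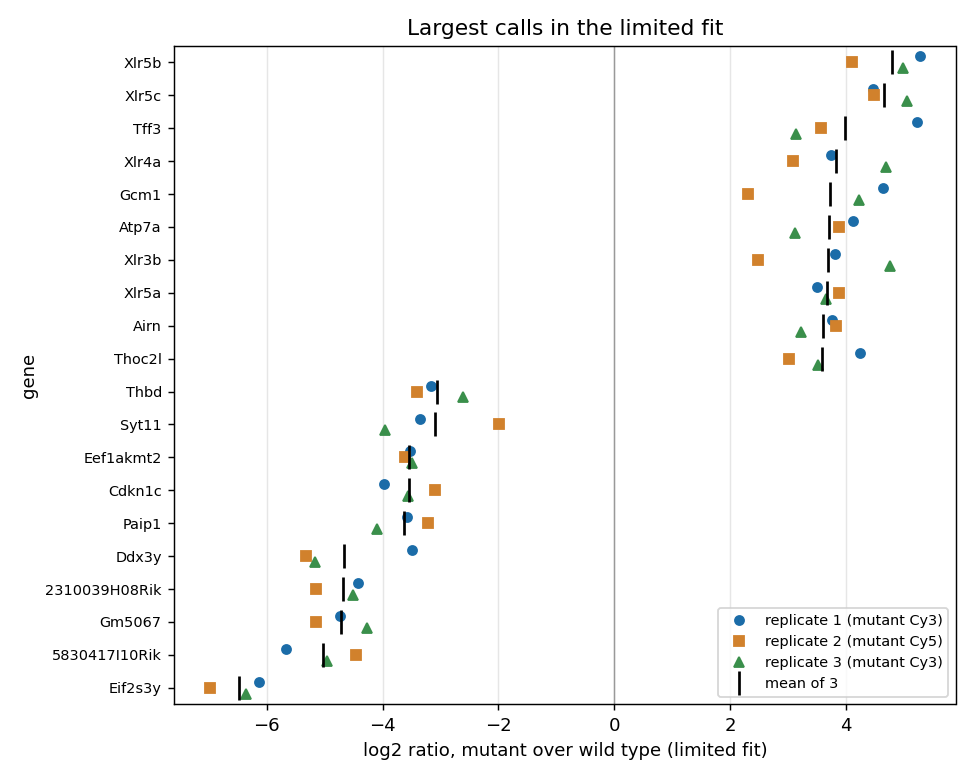
Log2 ratios of mutant over wild type (x axis) in the limited fit for the 10 higher and 10 lower called genes of largest size (y axis); symbols are the 3 arrays and black bars their mean. Each gene has one sign on all 3 arrays, and Eif2s3y, not well above background in the mutant, lies between -6.98 and -6.13.

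Groups of genes were compared through 34 lists fixed before the data were examined, of which 17 passed the camera test with a preset correlation in the planned fit and 18 in the limited fit. None of the 34 passed when the correlation was estimated from the 3 arrays, nor with fry, in either fit. The estimated-correlation adjusted p values are given with the lists. That test takes its degrees of freedom from the few arrays, and has fewer still with a replicate left out or a dye term. A list could hardly pass it, so not passing it says little about a list. With scaling between arrays 10 lists passed, and primitive endoderm regulators, parietal endoderm, definitive endoderm, trophoblast, imprinted, DNA replication and p53 genes did not. No member of any list passed the gene-level test over all genes in the planned fit, so member values, calls and counts adjusted over the list alone are those of the limited fit, and where 2 medians are given the planned fit comes first. In the planned fit the counts adjusted over the list alone were 20 for visceral endoderm, 13 each for cardiac muscle, mesenchyme and imprinted genes, 11 for parietal endoderm, 7 for definitive endoderm, 5 for trophoblast, 3 for BMP and TGF-beta targets, 2 each for endothelium and sex-linked genes, 1 each for primed epiblast, primitive streak, primitive endoderm regulators, 2-cell-like and p53 genes, and 0 for the others.

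Genes of the visceral endoderm and yolk sac, the extraembryonic tissue that secretes plasma proteins, were higher in the mutant. The median of 23 measured genes was 1.83 in the planned fit (adjusted p = 2.86e-14, and adjusted p = 0.632 with an estimated correlation) and 1.86 in the limited fit (adjusted p = 1.04e-12, and adjusted p = 0.577 with an estimated correlation). Of the 23, 22 were higher on all 3 arrays. In the limited fit 3 rose over all genes and 22 adjusted over the list alone. Ctsh, a lysosomal protease, rose to 1.88 ± 0.17 (adjusted p = 0.0393) and the thyroxine carrier Ttr to 2.62 ± 0.73 (adjusted p = 0.0460), and Apoc2 was at 2.28 ± 0.71 (adjusted p = 0.0519). Afp, alpha-fetoprotein, was at 2.33 ± 1.92 (adjusted p = 0.185), from 0.51 on array 2 to 4.34 on array 1.

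The other endoderm lists differed from one another. The 17 definitive endoderm and gut genes had a median of 0.50 in both fits (adjusted p = 0.00495 and 0.00401, and adjusted p = 0.632 and 0.535 with an estimated correlation), with 5 members risen in the limited fit. These included Tff3, the pioneer factor Foxa1 at 1.78 ± 0.37 and the keratin Krt19 at 1.69 ± 0.17, and adjusted over the list alone 6 rose and 1 fell. Without replicate 1, 2 or 3 the limited median of that list was 0.40, 0.85 and 0.26, each passing at the preset correlation. Among the 15 primitive endoderm regulators the median was 0.33 in the planned fit (adjusted p = 0.0395, and adjusted p = 0.700 with an estimated correlation) and 0.36 in the limited fit, which did not pass (adjusted p = 0.0517). Foxq1 rose to 2.01 ± 0.31, and adjusted over the list alone 3 rose. Hnf4a was at 2.06 ± 1.06, Fgfr4 at 1.06 ± 0.48 and Gata6 at 0.32 ± 0.65, none of them passing, and without replicate 1 the planned median was 0.21 and did not pass. The list also did not pass with no background correction, the scanner's log ratio, the mean of a gene's probes, a dye term or the authors' values (adjusted p = 0.0529, 0.105, 0.0732, 0.122 and 0.0507). The 15 parietal endoderm and basement membrane genes went the other way, with a median of -0.74 in the planned fit (adjusted p = 0.00383, and adjusted p = 0.632 with an estimated correlation) and -0.77 in the limited fit (adjusted p = 0.00548, and adjusted p = 0.577 with an estimated correlation). Thbd fell, Lama1, a laminin chain, was at -1.33 ± 0.43 and Srgn at -1.17 ± 0.27, and adjusted over the list alone 8 fell and 3 rose.

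Cardiac, mesenchymal and vascular genes were higher in the mutant. The 25 cardiac muscle genes had medians of 1.22 and 1.72 in the planned and limited fits (adjusted p = 3.46e-10 and 3.96e-10, and adjusted p = 0.632 and 0.535 with an estimated correlation), and 20 were higher on all arrays. In the limited fit 6 rose over all genes and 17 adjusted over the list alone, among them Tnnt2 and the heart transcription factors Hand2 at 3.03 ± 0.37 and Hand1 at 1.80 ± 0.29. The 19 mesenchyme and fibroblast genes had medians of 0.95 and 1.14 (adjusted p = 5.98e-07 and 2.52e-06, and adjusted p = 0.632 and 0.535 with an estimated correlation). Of these, 4 rose over all genes and 13 adjusted over the list alone, including smooth muscle actin Acta2 at 2.36 ± 0.13, Col1a2 at 2.84 ± 0.92 and fibronectin Fn1 at 1.79 ± 0.28. The 19 endothelium genes had medians of 0.44 and 0.64 (adjusted p = 0.00498 and 0.000848, and adjusted p = 0.632 and 0.535 with an estimated correlation). The VEGF receptor genes Flt1 at 3.06 ± 0.40 (8.32-fold) and Kdr at 2.26 ± 0.59 rose, 6 members did so adjusted over the list alone, and Mmrn2 was at 1.75 ± 0.60. Without replicate 2 the endothelium list had a median of 0.56 and did not pass. Its planned median was 0.22 without replicate 1 and 0.26 without replicate 3, both passing at the preset correlation. For 16 primitive erythroid and blood genes the medians were 0.37 and 0.46 (adjusted p = 0.0145 and 0.0103, and adjusted p = 0.655 and 0.621 with an estimated correlation), 0 members rose over all genes and 1 adjusted over the list alone. The embryonic globin genes Hbb-y and Hbb-bh1 were at 2.07 ± 1.45 and 1.07 ± 0.59 and Itga2b at 1.59 ± 0.47. The blood list did not pass without replicate 1 (0.18) or without replicate 2 (0.49). The 17 primitive streak and early mesoderm genes did not shift, with medians of -0.053 and -0.020, opposite in sign to the test (adjusted p = 0.765 and 0.932). In that list Hand1 rose, the only one adjusted over the list alone, T, brachyury, was at -0.67 ± 0.22 and Tbx6 at 0.60 ± 0.87.

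Neural genes were lower, mainly on arrays 1 and 3, the 2 with the mutant in Cy3. Array 2 alone has the dyes exchanged, so dye and replicate cannot be told apart here. In the limited fit 11 of the 20 neural progenitor and 12 of the 19 neuron genes were lower on all 3 arrays. The 20 neural progenitor genes had medians of -1.51 and -1.53 (adjusted p = 1.64e-08 and 5.93e-08, and adjusted p = 0.632 and 0.621 with an estimated correlation), but per array of the limited fit the median was -2.26, -0.092 and -2.63. None fell over all genes, and 9 did adjusted over the list alone. The Notch ligand Dll1 was at -1.88 ± 0.84, Sox3 at -2.12 ± 1.14 and the Notch target Hes5 at -3.12 ± 2.34, the last at -4.35, -0.43 and -4.59 on arrays 1, 2 and 3. The 19 neuron genes had medians of -1.02 and -1.07 (adjusted p = 0.00126 and 0.000534, and adjusted p = 0.632 and 0.621 with an estimated correlation), with array medians of -1.68, -0.19 and -2.04 and 8 members lower adjusted over the list alone. Stmn2 was at -1.74 ± 0.48, Stmn3 at -2.62 ± 1.47, Map2 at -2.70 ± 1.95 and Tubb3, neuronal tubulin, at -1.88 ± 1.23 (adjusted p = 0.134). The 11 neural crest genes did not shift, with medians of -0.083 and -0.21 (adjusted p = 0.642 and 0.774), 1 rose adjusted over the list alone, and Snai2 was at 2.60 ± 1.12, Mitf at -0.73 ± 0.15 and Ets1 at 0.78 ± 0.51.

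**Figure D3:**
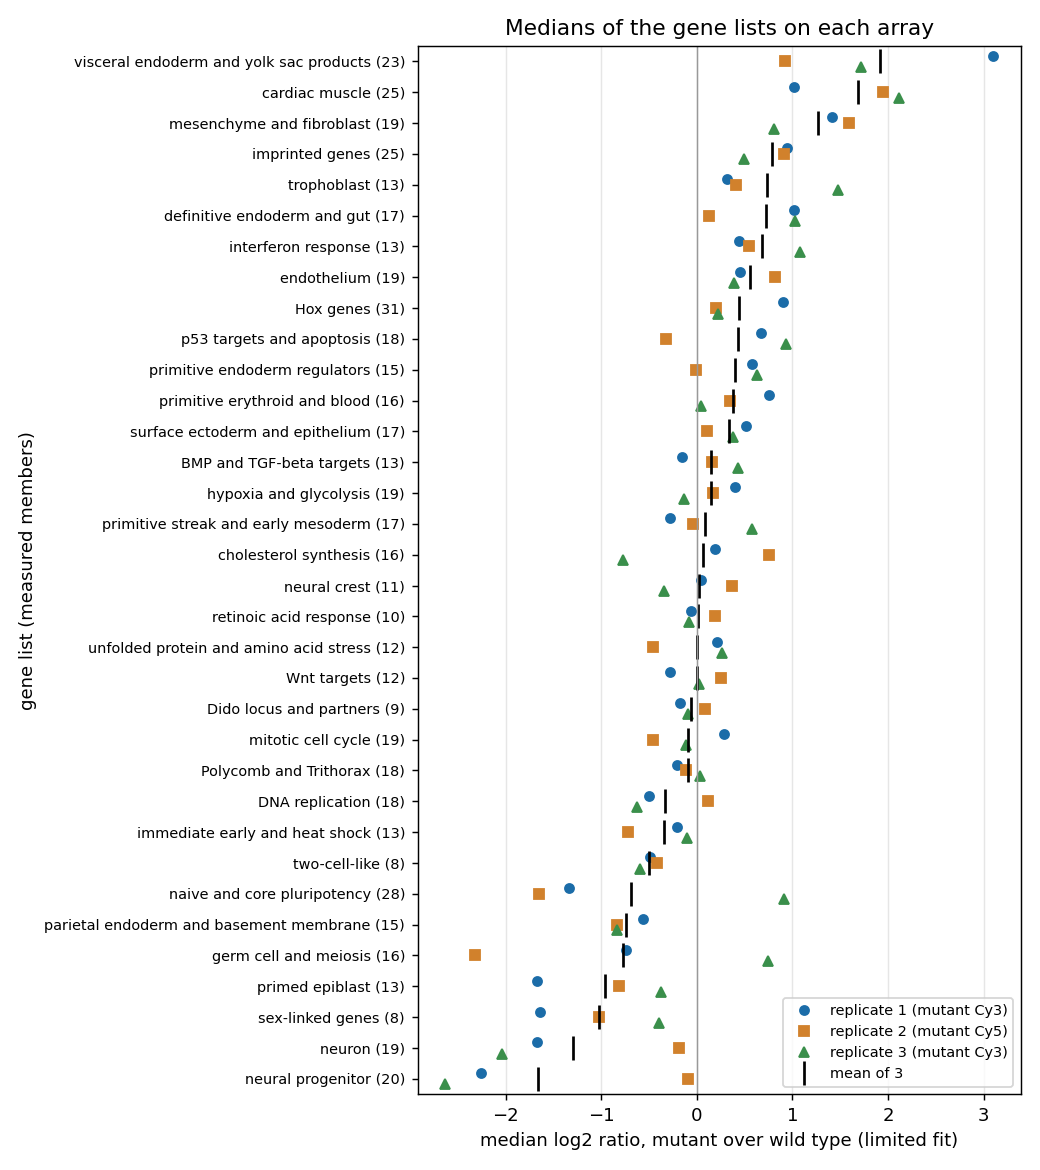
Median log2 ratio of mutant over wild type (x axis) of each of the 34 gene lists (y axis, measured members in brackets) on each array in the limited fit; symbols are the arrays and black bars the mean of the 3 medians. Visceral endoderm lies between 0.92 and 3.10, and neural progenitor genes at -2.26, -0.092 and -2.63 for replicates 1, 2 and 3.

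The median ratio of the pluripotency genes changed sign between arrays. The 28 naive and core pluripotency genes had a median of -0.23 in the planned fit (adjusted p = 0.476) and -0.51 in the limited fit (adjusted p = 0.273), with array medians of -1.34, -1.65 and 0.92. Pou5f1 was at -2.78, -2.62 and 0.89 on arrays 1, 2 and 3 (adjusted p = 0.381), Nanog at 0.23 ± 0.41, Fbxo15 at -2.73 ± 1.76, Tbx3 at 1.96 ± 0.78 and Tdh at 0.75 ± 0.28, and none passed. The 13 primed epiblast genes had a median of -0.55 in the planned fit, which did not pass (adjusted p = 0.0750), and -0.70 in the limited fit, which did (adjusted p = 0.0384, and adjusted p = 0.577 with an estimated correlation). Adjusted over the list alone 1 rose and 2 fell, with Cldn6 at 1.25 ± 0.13, Lefty1 at -2.77 ± 1.16 and Zic2 at -2.47 ± 1.60. The list named 2-cell-like, after genes active in the 2-cell embryo, had 8 measured genes with a median of -0.35 (adjusted p = 0.0624) and -0.56 in the limited fit (adjusted p = 0.0231, and adjusted p = 0.535 with an estimated correlation). Zscan4c fell to -2.42 ± 0.70 and 3 fell adjusted over the list alone, with Zscan4f at -2.24 ± 0.76 and Zfp352 at -0.98 ± 1.01. The Zscan4 genes are near-identical copies. The 16 germ cell and meiosis genes had medians of -0.0077 and -0.61 (adjusted p = 0.483 and 0.0579) with array medians of -0.74, -2.32 and 0.75. In it the meiotic gatekeeper gene Stra8 fell to -2.04 ± 0.48, the only one adjusted over the list alone, Rec8 was at -1.79 ± 0.95 and Prdm1 at 0.78 ± 0.33. Without replicate 3 the pluripotency list passed at -0.88 and -1.53 (adjusted p = 1.84e-10 and 4.04e-10), as did the germ cell list at -0.52 and -1.44 (adjusted p = 4.43e-06 and 1.02e-07) and the primed epiblast list at -0.84 in the planned fit. The primed epiblast list also passed in the planned fit with no background correction, the scanner's log ratio and the authors' values (adjusted p = 0.0406, 0.0230 and 0.0495), and the germ cell list with the scanner's log ratio (adjusted p = 0.0441). With an estimated correlation none of the 3 lists passed without replicate 3 (adjusted p = 0.629 each in the planned fit and 0.653 each in the limited fit). The visceral endoderm list had the same values in that test, so it does not tell these lists apart. Without replicate 2 the primed epiblast list (-0.72) and the 2-cell-like list (-0.50) did not pass in the limited fit, nor did the primed epiblast list with a dye term (adjusted p = 0.0904). With a dye term in the limited fit the germ cell list passed at -1.05 (adjusted p = 0.00772, and adjusted p = 0.779 with an estimated correlation). The 2-cell-like list passed at the preset correlation in the planned fit without replicate 1 (-0.32) or without replicate 3 (-0.39), and with an estimated correlation it passed in neither (adjusted p = 0.697 and 0.629). At the preset correlation it also passed with no background correction, the scanner's log ratio, median centring, the mean of a gene's probes, a dye term and the authors' values (adjusted p = 0.0258, 0.0224, 0.0249, 0.0113, 0.0344 and 0.0304). With a dye term and an estimated correlation it did not pass (adjusted p = 0.783), nor did the visceral endoderm list, at the same value.

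Imprinted genes, expressed from one parental copy, changed in both directions. The 25 measured genes had medians of 0.88 and 0.87 (adjusted p = 0.00495 and 0.0103, and adjusted p = 0.632 and 0.535 with an estimated correlation). In the limited fit 4 rose and 2 fell over all genes, and 9 rose and 5 fell adjusted over the list alone. H19 rose to 3.28 ± 0.42 (9.69-fold) and Airn 12.1-fold, while Cdkn1c fell and Igf2r fell to -2.19 ± 0.51. A second H19 probe read 0.98 ± 0.30, and other Airn probes read 3.26 ± 0.32, 2.18 ± 1.07 and 0.52 ± 0.20. Without replicate 2 the list had a median of 0.64 and did not pass. The 13 trophoblast genes had medians of 0.79 and 0.87 (adjusted p = 0.0346 and 0.0384, and adjusted p = 0.632 and 0.621 with an estimated correlation), with Cdx2 at 2.13 ± 0.58 and Hand1 risen over all genes, 6 risen and 1 fallen adjusted over the list alone, and Plac1 at 1.23 ± 0.27. That list did not pass without replicate 2 (1.03) or without replicate 3 (0.32), with a dye term in the planned or the limited fit (adjusted p = 0.0696 and 0.112), or with the scanner's log ratio (adjusted p = 0.0739).

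Among body-plan and response genes, 31 Hox genes had medians of 0.45 and 0.51 (adjusted p = 0.00355 and 0.000432, and adjusted p = 0.700 and 0.621 with an estimated correlation). No Hox gene rose over all genes or adjusted over the list alone, with Hoxb2 at 1.85 ± 0.63, Hoxc6 at 1.34 ± 0.59 and Hoxb4 at 0.97 ± 0.72, and without replicate 1 the planned median was 0.11 and did not pass. The 13 interferon response genes had medians of 0.53 and 0.57 (adjusted p = 0.00355 and 0.000534, and adjusted p = 0.632 and 0.535 with an estimated correlation). Usp18 rose to 1.58 ± 0.12, 5 rose adjusted over the list alone, and Ifit3 and Ifit2 were at 1.30 ± 0.20 and 1.03 ± 0.25. The limited median of that list was 0.92 without replicate 1 and 0.35 without replicate 3, both passing at the preset correlation. The 18 p53 targets and apoptosis genes had medians of 0.48 and 0.44 (adjusted p = 0.00498 and 0.0103, and adjusted p = 0.700 and 0.717 with an estimated correlation), a direction that turned to -0.073 with scaling between arrays. In it the death receptor gene Fas rose to 2.71 ± 0.60, the only one adjusted over the list alone, Cdkn1a was at 0.56 ± 0.20 and Plk2 at 0.88 ± 0.72, and without replicate 3 the planned median was 0.19 and did not pass. The 18 DNA replication genes had medians of -0.31 and -0.29 (adjusted p = 0.00498 and 0.0103, and adjusted p = 0.632 and 0.621 with an estimated correlation). None fell over all genes or adjusted over the list alone, with Tyms at -1.09 ± 0.78, Cdc6 at -0.61 ± 0.20 and Pold1 at -0.51 ± 0.17, and without replicate 3 the planned median was -0.174 and did not pass.

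The remaining lists did not shift in either fit. BMP and TGF-beta targets (13) had medians of 0.052 and 0.20 (adjusted p = 0.134 and 0.137). Smad6 rose to 1.68 ± 0.21, 3 members rose adjusted over the list alone, and Tgfbi was at 2.79 ± 1.25 and Msx2 at 0.77 ± 0.08. That list passed without replicate 1 (0.33 in the planned fit, and adjusted p = 0.697 with an estimated correlation) and in the separate-channel fit (adjusted p = 0.0378). Retinoic acid response genes (10) had 0.020, opposite in sign to the test, and -0.024 (adjusted p = 0.765 and 0.653). The retinol receptor gene Stra6 fell to -2.11 ± 0.14 (4.31-fold lower), the only one adjusted over the list alone, while Crabp2 was at -2.08 ± 2.13. No member of the following lists passed over all genes or adjusted over the list alone. Mitotic cell cycle genes (19) had -0.0018 and -0.024 (adjusted p = 0.563 and 0.460), with Ccnb2 at -0.60 ± 0.17, Bub1b at -0.39 ± 0.13 and Top2a at -0.49 ± 0.20. Surface ectoderm and epithelium genes (17) had 0.18 and 0.31 (adjusted p = 0.0965 and 0.0780), with Dsp at 1.49 ± 0.83, Dsg2 at 1.01 ± 0.39 and Cldn7 at 1.26 ± 1.06. Wnt targets (12) had -0.15 and -0.18 (adjusted p = 0.483 and 0.637), with Ccnd1 at -1.55 ± 1.51, Nkd1 at -0.79 ± 0.95 and Rnf43 at 1.22 ± 1.23. Hypoxia and glycolysis genes (19) had 0.071 and 0.050 (adjusted p = 0.341 and 0.437), with Slc2a1 at 1.26 ± 0.71, Hk2 at 1.43 ± 0.81 and Bnip3 at 0.57 ± 0.54. Immediate early and heat shock genes (13) had -0.0018 and -0.18 (adjusted p = 0.322 and 0.193), with Fosb at -1.10 ± 0.38, Dusp1 at -0.73 ± 0.54 and Atf3 at -0.72 ± 0.75. Genes of the unfolded protein and amino acid stress responses (12) had 0.019 and 0.029 (adjusted p = 0.641 and 0.653), with Psat1 at 0.96 ± 0.48, Vldlr at 1.48 ± 0.90 and Atf4 at -0.71 ± 0.34. Cholesterol synthesis genes (16) had 0.044 and 0.090 (adjusted p = 0.750 and 0.653), with Mvk at 0.44 ± 0.44. Polycomb and Trithorax genes (18) had -0.15 and -0.19 (adjusted p = 0.639 and 0.469), with Kmt2d at 1.08 ± 0.79, Cbx7 at 0.62 ± 1.89 and Ash2l at -0.35 ± 0.17. The Dido locus and partners list (9) had -0.076 and -0.087 (adjusted p = 0.639 and 0.653), with Tcea1 at -0.60 ± 0.26, Polr2a at -0.48 ± 0.61 and Dhx9 at 0.38 ± 0.28. In that list Dido1 stood by its brightest probe, the one nearest the 3' end, which did not pass. The other Dido1 probes, which passed in the limited fit, were not part of it. Without replicate 3 the hypoxia list passed at 0.36 and the cholesterol list at 0.46 in the planned fit (adjusted p = 0.629 each with an estimated correlation). With a dye term in the limited fit the surface ectoderm list passed at 0.29 (adjusted p = 0.0346, and adjusted p = 0.779 with an estimated correlation).

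Sex-linked genes were lower as a list, and the 2 members called lower were on chromosome Y. The 8 measured genes had medians of -1.06 and -1.31 (adjusted p = 0.0151 and 0.000942, and adjusted p = 0.632 and 0.535 with an estimated correlation). Eif2s3y and Ddx3y fell in the limited fit, 3 fell adjusted over the list alone, and the X-linked homeobox gene Rhox5 was at 0.58 ± 0.23. The list did not pass without replicate 2 (-1.35) or with no filter on dim probes (-0.075). In the limited fit without replicate 1 it passed at the preset correlation, at a smaller median of -0.71. The median does not move when Eif2s3y and Ddx3y are placed at their bounds. No tested chromosome shifted as a whole: of 20 chromosomes tested, with the X among them at a median of 0.025 in the planned fit and -0.0041 in the limited fit (801 genes), the smallest adjusted p was 0.939 in the planned fit and 0.916 in the limited fit. Chromosome Y had fewer than 50 measured genes and was not tested as a whole.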

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

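The limited fit and its alternatives were chosen after seeing the data, and the others before. Called genes (higher, lower), 0 in the planned fit, numbered 304 (231, 73) with no background correction, 768 (580, 188) with the scanner's log ratio, 665 (441, 224) with a dye term, 108 (83, 25) with separate channels and 357 (271, 86) with the limited background. Leaving out replicates gave 0 to 4977 (0 to 2995, 0 to 1982). The other planned settings gave 0. Genes 2-fold changed on every array, 302 in the planned fit, were 799 with no background correction, 1589 with the scanner's log ratio, 514 with the authors' values, 797 with the limited background and 318 to 2309 without single replicates. The Dido1 probes A_55_P2430472, A_52_P226127 and A_66_P128564 passed at 2.31, -3.53 and 3.05 with no background correction, at 3.03, -4.62 and 5.16 with the scanner's log ratio, at 1.43, -2.36 and 1.75 with a dye term and at 2.30, -3.55 and 2.98 with the limited background. Without single replicates they ranged from 1.34 to 2.48, -3.58 to -2.29 and 1.66 to 3.11, passing only without replicate 2. Probe A_51_P336385 ranged from -0.86 without replicate 2 to -0.0052 without replicate 1 and never passed. Shifted lists, 17 as planned, were 10 with scaling between arrays and 0 with an estimated correlation or fry. The p53 list median turned from 0.48 to -0.0734 with scaling between arrays. In the limited fit the 357 genes (271, 86) became 2452 (1503, 949) with a dye term, 716 (530, 186) with an offset of 16, 30 (19, 11) with the background limited at 1000 and 0 to 4977 (0 to 2995, 0 to 1982) without single replicates. Its 797 genes 2-fold changed became 934 to 2309 without single replicates, and its 18 shifted lists 0 with an estimated correlation or fry. All 357 genes kept their direction with no background correction and the scanner's log ratio, which read the same 3 arrays. With a dye term this was fixed in advance, since all 357 had one sign on every array. Calls with a dye term rest on the spread between arrays 1 and 3 alone, since array 2 is then fitted exactly. Calls without replicate 2 rest on 2 arrays of one dye orientation. The limit changed array 2 alone; for the other settings the cause was not tested. No tested chromosome shifted in the planned fit's settings or in the limited fit without each replicate, with a dye term, the filter on both genotypes, an offset of 16, the other limits or an estimated correlation. Limits of 150 and 200 gave 323 and 271 genes. Signal near background limits dim genes.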

Other observations

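The tests in this part were chosen after the results they concern had been seen, except those of probe GC content and of single-probe dye bias. The tests of lists on array 2, of chromosome Y probes and of imprinted genes were also redefined after a first form had given a value. Beyond the genes named by the rule, several further imprinted genes were looked at after their values were seen, all in the limited fit. Peg3 was at 2.96 ± 1.10 (adjusted p = 0.0548), Kcnq1ot1 at 2.52 ± 1.62, Igf2 at 2.10 ± 1.16, Meg3 at 1.32 ± 0.51, Slc22a18 at -1.78 ± 0.64 and Zim1 at -1.44 ± 0.67, none of them passing, while Dio3 rose to 2.18 ± 0.45 (adjusted p = 0.0418). In some clusters reciprocal genes differed in direction: Airn rose where Igf2r fell, and Kcnq1ot1 was higher where Cdkn1c fell. In others they did not: H19 and Igf2 were both higher, Meg3 and Mirg (1.84 ± 0.22) were higher together with Dio3, with Dlk1 at 0.27 ± 0.72, and Ascl2 of the Kcnq1ot1 cluster was at 0.87 ± 0.76. In the neural lists, Pax6, Sox1 and Fabp7 were at -3.73, -4.15 and -4.92 on array 1 and -4.47, -4.42 and -5.53 on array 3, against -0.40, -0.68 and -0.33 on array 2. Pax6 was well above background in the mutant on 2 of the 3 arrays, so its ratio is imprecise. In the pluripotency list, Zfp42 and Dppa3 were at 2.06 and 3.50 on array 3, against -1.94 and -0.90 on array 1 and -2.00 and -3.40 on array 2.

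One hypothesis is that imprint methylation is lost in the mutant cells. It was set against 29 measured imprinted genes whose direction after such a loss is textbook knowledge. Of the 18 with one sign on all arrays, all 11 that the loss would raise were higher, but 54.0% of all genes with one sign were higher, and of the 7 it would lower 57.1% were lower (4, with Ascl2, Igf2 and Dio3 higher). The first form of the test, over both kinds together, gave 83.3% in the direction of loss and did not separate the kinds. The hypothesis may hold for some clusters, and the genes it should lower leave it open. Genes of a cluster are not independent, and methylation was not analysed here.

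The planned fit called 0 genes. The bright patch in the local background of array 2 may account for this: limiting the background, which changed array 2 alone, let 357 genes pass and brought the SD of that array from 0.47 to 0.79, while higher limits of 150, 200 and 1000 gave 323, 271 and 30. But the authors' values also gave 0 genes in limma (smallest adjusted p of 0.0599). Their array 2 correlated at 0.991 with the limited fit and at 0.891 with the planned fit. The patch may therefore not be the only reason for a count of 0. Turning the sign of single arrays gives 4 arrangements of 3 arrays, too few for a share under 0.05. The real arrangement gave 357 genes in the limited fit (1 of 4 with as many) and the highest of the others 0, and in the planned fit all 4 gave 0.

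Array 2 correlated less with arrays 1 and 3 (r = 0.37 and 0.19 across genes of the limited fit) than these did with each other (0.79), and it is the array with the dyes exchanged. The mean of arrays 1 and 3 minus array 2 had a correlation of -0.376 across genes with probe GC content, and the ratios themselves had -0.227, 0.202 and -0.229 on arrays 1, 2 and 3 (chosen after), so a dye bias that depends on GC content may be part of it. Between non-overlapping probes of one gene, over 4422 pairs, that difference had a correlation of 0.361, which leaves a bias of single probes open, against 0.671 for the difference of arrays 1 and 3, which share their dyes. Cultures of replicate 2 in another state of differentiation stay open: 12 of the 34 lists differed on array 2 beyond the central 95% of 10000 random lists matched on signal and GC content (11 when matched on signal alone, the first form), but 15 did on array 1 and 20 on array 3, so this is not particular to array 2. Between arrays 1 and 3, which share their dyes, 22 of the 34 lists differed in the same way. Dye and replicate cannot be told apart with 1 array of that orientation.

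Eif2s3y and Ddx3y, both on chromosome Y, were far lower in the mutant on every array. In the limited fit Eif2s3y read -6.13, -6.98 and -6.35 on arrays 1, 2 and 3, and Ddx3y -3.485, -5.325 and -5.164. A pair exchanged on 1 array would turn the sign there, so these values argue against that. In addition, Eif2s3y was at least 89.6-fold lower on the mean of the 3 arrays and well above background on no mutant array. That argues against a large admixture of wild-type RNA into the mutant RNA. These values had been seen before the question was asked. Mutant cells without a chromosome Y remain a candidate explanation: of 9 probes of chromosome Y genes that were well above background in wild type, 77.8% were so on no mutant array, while 1 Uba1y probe was on all 3 (38.9% in the first form, over all 18 probes that the file places on chromosome Y). A second Uba1y probe was so on no mutant array, at -2.80 against -0.19, so the probes of that gene disagree. An active Xist, a sign of a second X, was seen in part, since both Xist probes were well above background on 1 mutant array, replicate 3, and on no wild-type array, and the X chromosome's median lay 0.033 ± 0.088 above that of the autosomes. Whether these Y-linked and the Xlr differences come from the lines' origin or from the mutation was not tested, and the strain and sex of the lines are not given in the sources used here.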
